A study of Caenorhabditis elegans with 4 samples.

How the data were processed

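Chromatin immunoprecipitation with sequencing was carried out on wild-type N2 Caenorhabditis elegans at the young adult stage, grown at 20 °C and crosslinked with 2% formaldehyde, per the labels' protocols. The antibody was 8WG16, a mouse monoclonal against the C-terminal repeat of the largest Pol II subunit, per the labels. The shared protocol text also speaks of embryos and of an anti-GFP serum, which differs from the stage and antibody that the sample labels give. The samples fell into 2 groups by their labels, immunoprecipitated DNA and input DNA, with replicates 1 and 2 in each. Nothing else about the separation of the replicates was used.

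The deposited list gave, for each region, a chromosome, a first and last base (1-based), and a q-value, per the file headers and columns. Regions were called with PeakSeq on WormBase build WS180, per the file headers; the version, aligner, read filters and the way replicates were combined are not given in the sources used here. All q-values were below 0.01. The list was tested to hold the same q-value in both of its q-value columns in 1310 of 1310 regions. No table of reads or signal was used, so the total depth of the libraries is unknown.

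The gene table at hand was of assembly WBcel235, which is not the build of the list. Coordinates were not converted between builds, so no region was assigned to a gene. The planned tests of promoters, gene ends, gene bodies, gene lists, RNA gene classes, GC content and scores at ribosomal protein genes were therefore not run. In their place regions were named by position, by a rule set before the data were examined: the 10 most significant and the most significant of each chromosome. Lengths of WS180 chromosomes were not at hand either, and the end of the last region on each chromosome was used in their place (99.99 Mb in all).

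Tags were recovered from the q-values. A q-value that is a p-value multiplied by the number of tests and divided by its rank was searched for over first ranks from 1 to 100 and totals up to 50000, taking as p the upper binomial tail at odds of 0.5 for whole numbers of ChIP and control tags. A first rank of 30 and a total of 14435 matched. With them, 1301 of 1310 regions (99.3%) had exactly 1 pair of tags within a relative tolerance of 1e-10, while ranks lower or higher by 1 matched 0. The reading of the larger number as ChIP tags and the other as control tags after scaling follows the published PeakSeq procedure and is not stated in the file. On each chromosome the recovered control tags were then fitted as whole numbers times 1 factor, rounded up, which held for 96.6 to 98.6% of them. On simulated tags (1306 regions with known tags and factors) the search returned the right rank and total, and both tag numbers in 99.8% of regions, with a wrong pair in 0.153%. The simulation searched a narrower range of totals and left out the smallest p-values. It also built its q-values with the same tail and rounding that the search assumes, so it cannot check that reading. Intervals of ratios are exact (Clopper-Pearson, 95%) on ChIP and unscaled control tags and cover counting error only.

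Shares were tested with exact two-sided binomial tests, pairs of shares with Fisher's exact test, medians with 100000 permutations, and positions with 10000 random placements of the regions along their own chromosome or, added after seeing the data, within its left, central or right part. The comparisons of X with the length, of the central 33.3% of autosomes, and of neighbouring regions were set before the data were examined. The comparisons of chromosomes I and IV, of X with the autosomes in its central part, of single chromosomes, of region lengths and ratios, of 1 Mb windows, of chains and of control factors were added after seeing the data. Alternatives were the 655 more significant regions, merged neighbours, covered bases, other distances and, added after seeing the data, 1 control factor for every chromosome (the median of the 6, 1.74, or the largest, 1.83), subsets of chromosomes, regions of at least 200 bp, and all 29 absent top-ranked regions placed on X. Regions that a factor below a chromosome's own would have added could not be restored, which concerns the median factor on II, V and X but not the largest. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.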

Results

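Chromatin occupied by RNA polymerase II (Pol II), the enzyme that transcribes protein-coding genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in young adult hermaphrodites of N2, the wild-type laboratory strain of Caenorhabditis elegans. The series held 4 libraries: 2 replicates of immunoprecipitated DNA and 2 of input DNA, the unselected chromatin that serves as control. The values came from 1 list of enriched regions that combined both replicates, so there was no replicate check on any value below and no error between worm cultures could be given. The total depth of each library is unknown. The list named regions by position in genome build WS180 and gave no genes, so regions are identified here by chromosome, start and end. Tests below took regions as units, and regions are not independent replicates of the experiment. Regions also lay in groups, so tests and intervals that treat them as independent draws give p-values that are too small and intervals that are too narrow.

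The first question was where Pol II was enriched and how strongly. The list held 1310 regions on the autosomes I to V and on the X chromosome, together covering 3482 kb. Regions were long: the median length was 2032 bp (quartiles 893 and 3796 bp), and 19 regions reached at least 10000 bp. For 1301 regions the q-value gave back the numbers of ChIP and scaled control tags (sequenced fragments) behind it. These regions held a median of 435 ChIP tags (quartiles 192 and 938) against a median of 249 scaled control tags. Enrichment was moderate for most regions, with a median ratio of ChIP to scaled control tags of 1.82 (quartiles 1.54 and 2.27). The ratio was under 2 in 802 regions and over 4 in 29.

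The most significant listed region of all lay on chromosome I from 5372146 to 5382054, with a length of 9909 bp and a q-value of 4.81e-306. The region on chromosome II from 6342598 to 6349611 followed with a q-value of 1.40e-305. Chromosome X supplied 3 of the 10 most significant regions: 4136679 to 4149242, with a length of 12564 bp, 1502644 to 1505165, with a length of 2522 bp, and 12662132 to 12669222, with a length of 7091 bp. The others among the first 8 were chromosome I from 9378390 to 9384449, chromosome IV from 16167266 to 16171722, and chromosome V from 11884188 to 11890035. The p-values that the q-values of these 8 imply have 1 digit each, and no tags were recovered for them. The ninth, on chromosome I from 8865096 to 8868857, held 2037 ChIP tags against 352 scaled control tags, a ratio of 5.79 (95% exact interval 5.09 to 6.63). The tenth, on chromosome II from 6887617 to 6893211, held 3412 against 1067, a ratio of 3.20 (95% exact interval 2.93 to 3.50). The highest-ranked region of chromosome III, from 8443238 to 8449836, held 3741 against 1268, a ratio of 2.95 (95% exact interval 2.72 to 3.20). The ratio on chromosome I thus exceeded those on II and III by more than the counting error. These intervals cover counting error only, since tags amplified by PCR are not independent molecules. The ranking concerns the regions listed, because the q-values place the first of them at rank 30 of 14435 regions tested. The 29 regions ranked above it are not analysed here.

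Over the whole list, longer regions tended to have lower ratios. The longest region, on chromosome III from 7718386 to 7738395, spanned 20010 bp with a ratio of 1.502 (95% exact interval 1.43 to 1.58). The next longest, on X from 11468604 to 11486250, spanned 17647 bp with a ratio of 1.71 (95% exact interval 1.62 to 1.82). High ratios occurred at several lengths. On chromosome V from 9088575 to 9089303, 514 ChIP tags stood against 72 scaled control tags in 729 bp (ratio 7.14, 95% exact interval 5.22 to 10.1), and the 2609 bp on chromosome V from 7414659 to 7417267 had a ratio of 5.24 (95% exact interval 4.47 to 6.19). These regions were chosen after their values were seen. Over the 1301 regions, Pearson's r between the log10 length and the log10 ratio was -0.32 and Spearman's rho -0.22 (permutation p = 1e-05 for each, two-sided, the smallest that 100000 permutations can give). Without the 2 regions farthest from the median length r was -0.30. The ratios pool chromosomes whose control was scaled by unlike factors. Chromosome I, with a factor of 1.36, had a median length of 1277 bp and a median ratio of 1.97. Chromosome X, with a factor of 1.80, had 3155 bp and 1.65. Without scaling, the median ratios were 2.67 on I and 2.97 on X, but selection against scaled control lets lower unscaled ratios into the list on I. The relation was not computed within chromosomes or without scaling. The q-value threshold shapes this relation: regions with fewer than 100 tags in all entered the list only with ratios of at least 1.97, whereas the 203 regions with more than 2000 tags reached down to 1.13. The 650 more significant regions with tags were both longer (median 3318 against 1090 bp) and higher in ratio (median 2.05 against 1.62) than the other 651. Significance is computed from the same tags, so this split favours higher ratios and more tags by construction.

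**Figure D1:**
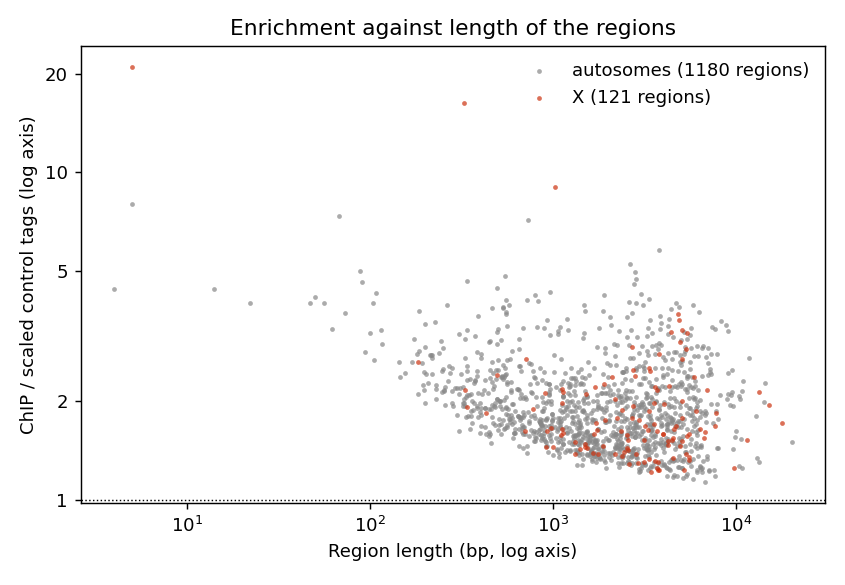
Ratio of ChIP to scaled control tags against region length, both on log axes, 1 point per region with recovered tags; X regions in red, autosomal regions in grey, dotted line at a ratio of 1. The lower edge of the cloud falls with length. The 3 topmost X points rest on few control tags.

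The second question was how Pol II regions were spread over the 6 chromosomes. The X chromosome carried fewer regions than its length: 124 of 1310, or 9.47% (95% exact interval 7.93 to 11.2%), against 17.6% of the summed chromosome lengths (exact two-sided binomial test, p = 8.87e-17). That is 7.03 regions per Mb on X (95% Poisson interval 5.85 to 8.38). Among the autosomes, chromosome V was lowest with 8.44 per Mb (7.24 to 9.79), an interval that overlapped that of X. Chromosome V also fell below its length share, with 13.4% of regions on 20.8% of the length, which was not tested on its own. Chromosome II followed with 11.6 per Mb (9.91 to 13.4) and III with 15.5 (13.5 to 17.8). Chromosome IV had 16.996 per Mb (15.12 to 19.04) and chromosome I 21.5 (19.2 to 23.9). The 6 chromosomes differed by more than independent counting gives (chi-square 194 against 100000 random multinomial draws, p = 1e-05, the smallest that these can give). After regions within 5000 bp were merged, X held 10.7% of 933 regions (exact two-sided binomial test, p = 5.69e-09). The lower X share also held among the more significant regions: 72 of the first 655 lay on X, or 11.0% (exact two-sided binomial test, p = 2.86e-06).

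Chromosomes I and IV together held 620 regions, 47.3% of the list against 32.5% of the length (exact two-sided binomial test, p = 1.32e-28). After regions within 5000 bp were merged, the share was 43.4% of 933 (exact two-sided binomial test, p = 4.64e-12). The pair was picked because its densities were the highest in this list, and the p-values carry no correction for that choice. The excess depended on how the control was scaled. The control tags on each chromosome were multiples of 1 factor, which was 1.36 on I and 1.39 on IV but 1.74 on III, 1.75 on V, 1.80 on X and 1.83 on II. With the largest factor, 1.83, for every chromosome, the control falls nowhere, so this scaling can remove regions but leaves none to be added on any chromosome. It raises the control most on I and IV, whose own factors were lowest, so a larger loss there was built in. The p-value limit of the list then kept 947 regions, of which 305 lay on I and IV, or 32.2% (95% exact interval 29.2 to 35.3%; exact two-sided binomial test, p = 0.862). Chromosome I then had 10.0387 regions per Mb and chromosome IV 8.81, between the 7.53 of V and the 13.6 of III. The X share was still below its length share, with 122 of the 947 regions, or 12.9% (exact two-sided binomial test, p = 8.48e-05). Among only II, III, V and X, whose factors were alike, X held 17.97% of regions against 26.1% of the length (exact two-sided binomial test, p = 4.62e-07).

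**Figure D2:**
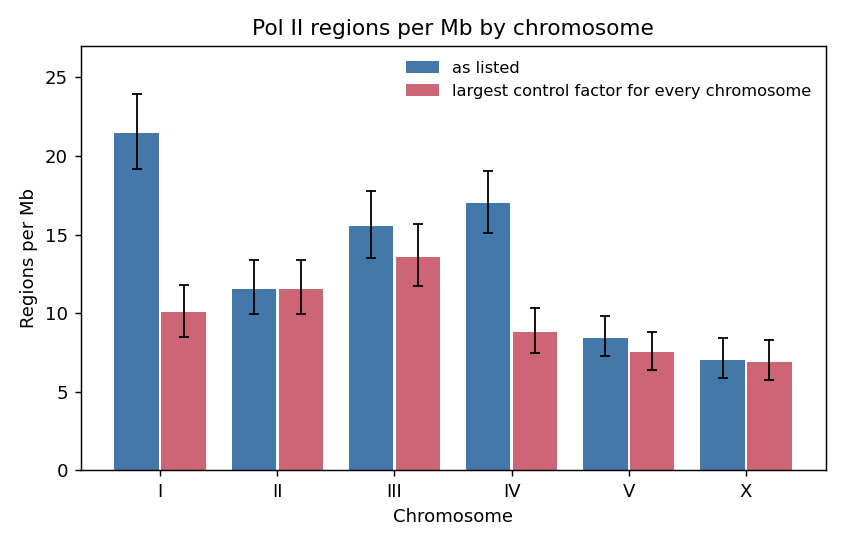
Regions per Mb on each chromosome, as listed (blue) and with the largest control factor for every chromosome (red); bars start at 0 and error bars are 95% Poisson intervals of the counts. Chromosome I falls from 21.5 to 10.0387 per Mb and IV from 16.996 to 8.81, while X is lowest in both, at 7.03 and 6.92. The intervals of X and V overlap in both.

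X regions were longer than autosomal ones. Their median length was 3155 bp on X (124 regions) against 1889 bp on the autosomes, a ratio of 1.67 (95% bootstrap interval 1.32 to 1.98; permutation test, two-sided, p = 7e-05). Against II, III and V alone, with a median of 2416 bp, the ratio was 1.31 (1.04 to 1.54; permutation test, p = 0.0177), and it was 1.197 (permutation test, p = 0.143) after regions within 5000 bp were merged. As a share of covered bases X reached 12.9%. Scaled enrichment on X was slightly lower than on the autosomes, with median ratios of 1.65 and 1.84 (permutation test, adjusted p = 0.00386 over 6 comparisons). Against II, III and V, at 1.77, this difference did not pass the correction (permutation test, adjusted p = 0.0606). Neither did unscaled ratios, at 2.97 on X against 3.13 on II, III and V (permutation test, adjusted p = 0.129). Against all autosomes, at 2.87, the unscaled ratio was higher on X and did not pass (permutation test, adjusted p = 0.299). The remaining comparisons, of I and IV with II, III and V, passed in opposite directions. Scaled medians were 1.92 against 1.77 (permutation test, adjusted p = 0.00015) and unscaled ones 2.63 against 3.13 (permutation test, adjusted p = 6e-05). Regions were selected against scaled control, so the lower factors of I and IV let in lower unscaled ratios there. The unscaled difference was thus built in, at least in part, and its p-value is no evidence of weaker enrichment. The same selection bears on the unscaled comparison of X with all autosomes. The direction of the difference between X and all autosomes thus depended on the scaling. Ratios were not adjusted for region length or tags, although X regions were longer and longer regions tended to have lower scaled ratios.

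The third question was where regions lay along each chromosome. Autosomal regions lay more often in the central part of their chromosome than its length gives: 569 of 1186, or 48.0% (95% exact interval 45.1 to 50.9%), had their midpoint in the central 33.3% of the chromosome by length (exact two-sided binomial test, p = 2.40e-25). Each autosome passed the test on its own over 6 chromosomes (exact binomial tests, Benjamini-Hochberg adjusted p at most 0.00208). The share was 53.6% on I, 52.8% on V, 45.3% on III, 44.9% on II and 42.8% on IV. The X chromosome did not show this, with 37 of 124 regions, or 29.8% (95% exact interval 21.96 to 38.7%), in its central part. X differed from the autosomes (Fisher's exact test, odds ratio 0.46, p = 0.000136). After regions within 5000 bp were merged, the central share of the autosomes was 45.4% of 833 regions (exact two-sided binomial test, p = 5.87e-13). The outer parts were unequal on some autosomes. Chromosome II had as many regions in its right part as in its centre, 79 each, and 18 in its left part, so its higher central share reflects the sparse left part. Chromosome IV had 127 in its centre, 110 in its left part and 60 in its right part.

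In the list as given, the window from 7 to 8 Mb on chromosome I held 52 regions, the most of any 1 Mb window, and the window from 9 to 10 Mb there held 45. The window from 1 to 2 Mb on chromosome II held 0, and the one from 3 to 4 Mb there held 1. The high counts on chromosome I depended on its control factor: with the largest factor for every chromosome these windows kept 21 and 22 regions, and the fullest was 5 to 6 Mb on chromosome III with 26. With regions placed at random along the whole chromosome, the fullest window had a median of 30 regions for the list as given (permutation of positions, p = 1e-04, the smallest that 10000 draws can give) and 20 with the largest factor (permutation of positions, p = 0.0141). With regions placed within their own part of the chromosome (left, central or right), which keeps the central rise and was chosen after seeing the data, the medians were 41 for the list as given (permutation of positions, p = 0.0057) and 23 with the largest factor (permutation of positions, p = 0.144). Once regions within 5000 bp of each other were merged, the fullest window held 22 merged regions against a random median of 23 (permutation of positions, p = 0.773). Merged regions cannot lie within 5000 bp of each other, whereas the random positions could. The comparison is thus tilted towards a low observed count and cannot show that crowding was absent.

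**Figure D3:**
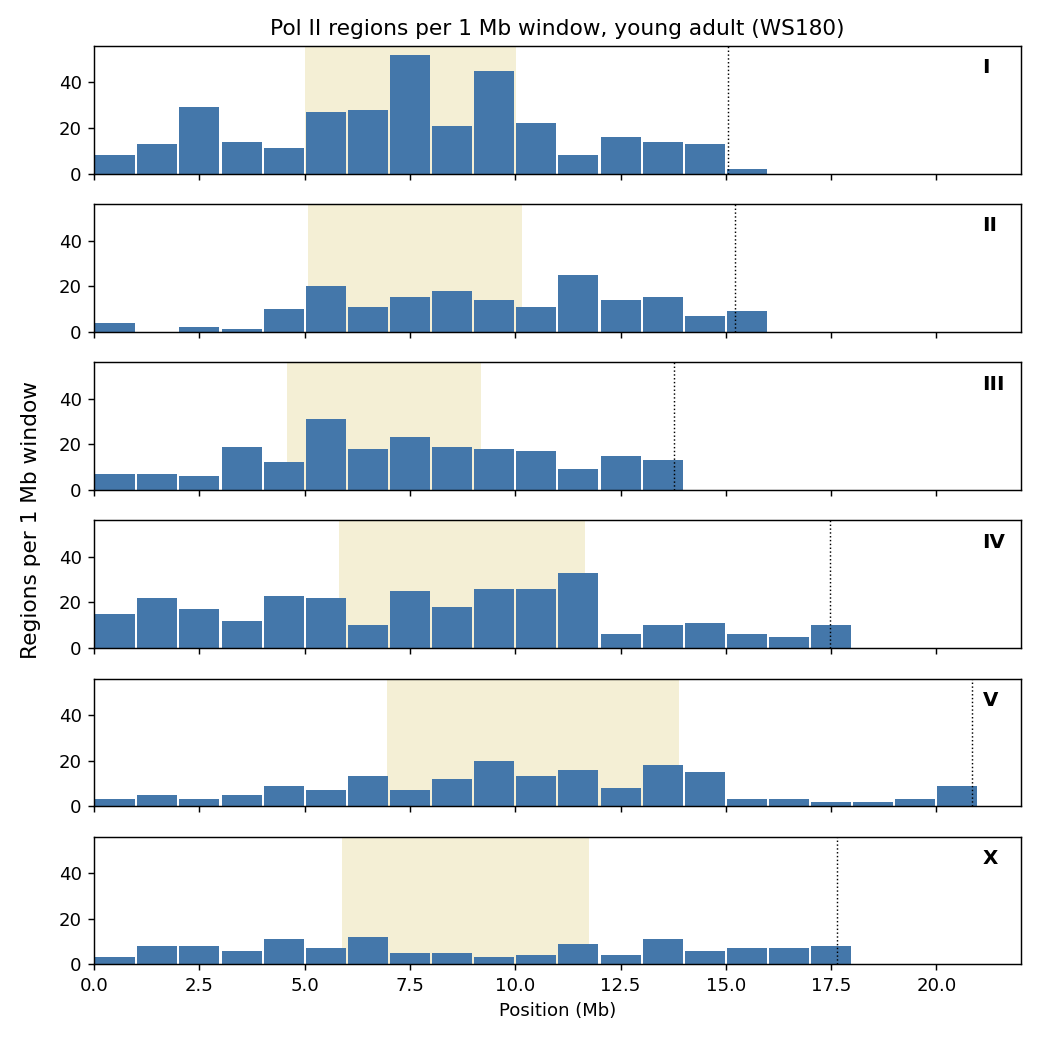
Number of regions whose midpoint lies in each 1 Mb window along the 6 chromosomes; shading marks the central 33.3% and the dotted line the end of the last region, past which the last window is empty. Windows 7 to 8 Mb and 9 to 10 Mb of chromosome I hold 52 and 45 regions, while the X profile has no central rise.

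Neighbouring regions often lay close together. Of the 1310 regions, 488, or 37.3%, had another region's midpoint within 5000 bp, against 13.8% for randomly placed regions (95% of draws between 11.3 and 16.3%; permutation of positions, two-sided, p = 0.0002, the smallest that 10000 draws can give). The richest chain, in which no gap exceeded 5000 bp, lay on chromosome I from 7570666 to 7586140 and held 10 regions in 15475 bp. A chain of 9 regions ran from 2853609 to 2879016 on the same chromosome. With the largest control factor, 5 of the 10 and 7 of the 9 were left. On chromosome III, 5 regions formed a chain from 12595544 to 12623808, a span of 28265 bp, and all 5 were kept. Neighbours were never closer than 200 bp. After regions within 1000 bp were merged, 120 of 1087, or 11.0%, still had such a neighbour, against 11.3% at random (permutation of positions, p = 0.867), although merging itself removes the closest neighbours.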

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

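Of the alternatives in this part, those with 1 control factor, fewer chromosomes, regions of at least 200 bp or absent regions, and all for I and IV and for region length, were added after seeing the data. So were merging before neighbours were counted and placement within parts of a chromosome. The share of regions on X, in the central part of autosomes and on I and IV was recomputed under 19 alternatives in all. Covered bases, used in 2 of these, carry no test; of the others, only the I and IV share changed its call. It fell to 33.7% of 1040 regions with the median control factor for every chromosome, which removed regions on no other chromosome, and to 32.2% of 947 regions, just under the 32.5% of length, with the largest factor. As covered bases, X made up 12.9%, outside the interval of its share of regions. The X share stayed between 9.57 and 17.97% otherwise, the highest being among II, III, V and X alone, where the length share is 26.1%; with all 29 absent regions placed on X it was 11.4%. The more significant part of the list held 655 regions by construction, and merging within 1000 bp left 1087. Of 7 alternatives for neighbouring regions, 6 kept the excess, down to 4.35% against 2.94% at random within 1000 bp; placement within parts gave 15.3% at random. Merging within 1000 bp first turned the excess to 11.0% against 11.3%, in part because merging removes the closest neighbours. The longer X regions kept their direction in 6 alternatives, with length ratios between 1.197 and 1.63, and lost the call at 1.197 after merging within 5000 bp; the cause was not tested. Depth limits ratios in short regions: with under 100 tags, no ratio below 1.97 was listed. No paired analysis was possible because the list combines both replicates, and for the same reason no replicate could be left out. Expected shares from gene numbers and every alternative for promoters, gene ends, gene bodies, gene lists, RNA gene classes, GC content and ribosomal protein genes were not run, since the gene table was of another build.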

Other observations

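All tests and regions in this part were chosen after the results were seen. Among regions of at least 500 bp with recovered tags, which leaves out the 8 most significant listed, the most ChIP tags per kb were found on chromosomes II and V. There, chromosome II from 5844572 to 5845286 had the most ChIP tags per kb, 1113, with 796 ChIP tags against 195 scaled control tags (ratio 4.08, 95% exact interval 3.34 to 5.07). Chromosome II from 12944163 to 12945089 followed with 950.4 per kb (ratio 3.55), and chromosome II from 14017939 to 14018494 with 839.9 (ratio 3.38). Control was high in these regions too, at 272.7, 267.5 and 248.2 scaled tags per kb, against a median of 146 over the listed regions of chromosome II. On chromosome V, the region from 9338390 to 9338918 had 799.6 per kb (ratio 3.88, 206 scaled control tags per kb). The 3335 bp from 9342856 to 9346190 had 724.7 (ratio 4.10, 177 scaled control tags per kb). The median of scaled control over the listed regions of chromosome V was 141.5. The median region of each chromosome was far lower, from 197 per kb on IV to 256 on III. The tags were unevenly shared: the 130 regions with the most ChIP tags, 10% of those with recovered tags, held 33.9% of all ChIP tags in regions. At the other end, chromosome III from 13616773 to 13623493 was listed with 1454 ChIP tags against 1286, a ratio of 1.13 (95% exact interval 1.03 to 1.24).

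Chromosomes I and IV carried more regions per Mb than II, III and V, but the control was scaled by 1.36 and 1.39 there and by 1.74 to 1.83 elsewhere. The pattern may come from this scaling: with the largest factor for every chromosome, the higher of I and IV had 10.0387 regions per Mb, inside the range of 7.53 to 13.6 on II, III and V. That factor raises the control most on I and IV, so a fall there was built in and only its size was left to the data. Lower control coverage on I and IV stays open, because control tags were known only within listed regions, which were selected against their control. Within these regions, unscaled control tags per kb had a median 0.991 times that of II, III and V when I and IV were pooled. The median was 1.07 times on I (95% bootstrap interval 1.02 to 1.11) and 0.927 times on IV (0.903 to 0.965). These values do not measure the coverage of the whole chromosomes. The factors themselves are read from the control tags, of which at least 96.6% on each chromosome were multiples of the factor rounded up. Once each was shifted at random by up to 10 tags and a new factor was fitted, the share was at most 83.5%. The new factors could differ, and the share that fits by accident falls with the factor, so the shares are not strictly alike. Whether the lower factors reflect a real lower ChIP background on I and IV stays open, and so does a difference in gene activity between chromosomes, which was not tested.

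The list starts at rank 30, so the 29 regions ranked as more significant are not analysed here. A candidate explanation is that their p-values were too small to be stored: the q-value of the first listed region, times its rank and over the number of tests, gives 1e-308, near the smallest normal double-precision number of 2.23e-308, and the ranks ran without a gap to 1339. The match of 1301 q-values to exact binomial tails at these ranks could have failed and did so at ranks moved by 1. The most significant Pol II regions of young adults may thus be missing from any ranking made with this list. Their ratios are unknown, and rank by significance is not rank by ratio.

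On the right arm of X, 3 adjacent regions starting at 16933809, 16935168 and 16936704 had few control tags to set a ratio against. The ratio was 9.04 in the first (95% exact interval 5.31 to 17.7) and 16.3 in the second (4.80 to 152). The third spans 5 bp, and its 1 scaled control tag is no multiple of the X factor of 1.80 rounded up. Its unscaled control tags are therefore unknown, and no interval of its ratio is given. Together they held 303 ChIP tags against 29 scaled control tags, which is 21.6 control tags per kb where the other X regions had a median of 128. Their 225 ChIP tags per kb were near the median of 212 in the other X regions and below the 90th percentile of 365. What lowered the control there, such as poor mappability, was not tested, as no genome sequence was at hand.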
